A study of Drosophila melanogaster with 34 samples.

How the data were processed

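The series studied RNA from ovarian somatic cells (OSC), a cultured Drosophila cell line of the somatic cells that surround the germline in the ovary. The cells have the nuclear branch of the piRNA pathway, in which the Argonaute protein Piwi, guided by piRNAs, silences transposable elements (TEs). Genes were knocked down with siRNA, and poly(A) RNA was sequenced. The targets were Smt3 (the SUMO protein), Su(var)2-10 (a SUMO ligase, labelled Suv210), Panx (Panoramix, a partner of Piwi), Piwi, Sov (Small ovary), PNUTS (a subunit of a nuclear phosphatase complex), Setx (the Drosophila senataxin helicase) and PNUTS with Setx. The LacZ siRNA has no target in the fly and was the control. The labels number a pair of Smt3 knockdown groups 1 and 2 without saying what differs between them. Of the 34 samples of the series, 26 RNA libraries in 13 groups of 2 had a file and were analysed. The other 8 samples, 2 RNA libraries with tethered Panx and 6 libraries of ChIP-seq for RNA polymerase II phosphorylated on Ser5, had none and are not analysed here. Nothing in the labels says whether the replicates were separate cultures.

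The deposited tables hold expected counts, that is, fractional read counts per repeat name on genome build dm6, with all annotated copies of a name added up and no scaling for depth, per the file headers and the values. The authors' processing notes name Trim Galore 0.6.7, STAR 2.7.10a, Bowtie2 2.2.5, featureCounts 2.0.1 and deepTools 3.5.1 without giving each one's role or settings. How reads matching several places were counted, and on which strand, is not stated. Each table has 9263 repeat names, of which 9034 are simple or low-complexity repeats and 229 are named repeats. Of the named ones, 206 are TE entries (132 LTR, 40 LINE and 34 DNA transposon), 5 are satellites, 6 were grouped as structural RNAs and 12 are others. The LTR and the internal part (suffix I-int) of a retrotransposon are separate entries, so one element can appear as a pair. The tables have no genes and no single TE copies. The knocked-down genes, marker genes and single insertions could therefore not be measured, and how well each knockdown worked is unknown.

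Counted repeat reads per library ranged from 679372 to 1971951. These are reads on annotated repeats alone, so the sequencing depth is unknown. The ranges were 679372 to 1267633 in set 1, 1113515 to 1971951 in set 2 and 1319006 to 1599903 in set 3. Values are CPM (counts scaled to 1e6 counted repeat reads) after TMM scaling over all repeats, so a fold change is relative to the other repeat RNA, mostly reads in simple repeats. Such reads can come from many transcripts. The log2 fold changes carry approximate standard errors (SE), the size of the change divided by the square root of its F statistic. CPM means carry SDs over the 2 libraries of a group. Intervals for entries with few counts cover counting error only.

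Libraries were compared with the LacZ libraries of their own set. Set 1 holds the first LacZ group, both Smt3 groups, Su(var)2-10, Panx and a Piwi knockdown. Set 2, marked in the labels, holds a LacZ group, a second Piwi knockdown and Sov. The labels do not say which LacZ group belongs to PNUTS, Setx and their double knockdown. The third LacZ group, which is matched to no other knockdown, was used, and these 4 groups form set 3. The mean Pearson r of simple-repeat levels between the Setx libraries and LacZ of sets 1, 2 and 3 was 0.950, 0.970 and 0.988. This measure does not always pick the assigned control: Panx had 0.967 with LacZ of its set 1 and 0.972 with LacZ of set 2, and Piwi of set 1 had 0.969 and 0.971. The other choices of control are among the alternatives.

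Expected counts were rounded and tested in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1): TMM scaling over all repeats, a low-count filter (filterByExpr, minimum count of 10), and a quasi-likelihood fit of all 26 libraries with 1 mean per group, which leaves 13 residual degrees of freedom. Of the 206 TE entries, 193 passed the filter; they belong to 136 families. P-values are two-sided, adjusted over the 193 entries by the Benjamini-Hochberg method, and an entry is called at an adjusted p under 0.05. The fit gives an entry the same spread in all groups, but replicates were not equally close. Chi-square over degrees of freedom between replicates, over all repeats with at least 10 counts, is near 1 for counting error alone. It ran from 1.92 to 5.12 in set 1 (LacZ 4.89), 1.79 to 2.24 in set 2 and 1.33 to 2.18 in set 3. P-values may thus be too small in set 1 and too large in set 3. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the plots. On simulated data with the real library sizes and 2 libraries per group, entries were raised in the Setx group, Smt3 group 1 or the Sov group. The test recovered 17, 18 and 16 of 20 entries changed 1.5-fold, and 20 of 20 at 2-fold and at 4-fold. It called 1 of 121, 2 of 120 and 5 of 120 unchanged entries. The simulation gave all groups the mean LacZ profile and all entries the same spread, without differences between sets. Raised entries were all above 20 CPM, so low entries and a rise of most TEs were not covered.

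The comparisons were each knockdown against LacZ, the double knockdown against each single one, the interaction of PNUTS with Setx (double minus both single effects), one Smt3 group against the other, the Piwi effect in set 2 against that in set 1, and the LacZ groups of different sets against each other. The direct contrasts of Panx, Smt3 (mean of both groups), Su(var)2-10 and Sov with Piwi, of Su(var)2-10 with Smt3, and of Setx with PNUTS were chosen after the first results were seen. Overlaps of called entries with those of Piwi used the Piwi knockdown of another set, so that no control library was shared. They were tested with Fisher's exact test, one-sided, adjusted over 18 tests. It treats entries as independent, although the LTR and internal part of an element are linked. Each of 8 fixed lists was counted and tested with camera (preset correlation of 0.01) within each knockdown: errantiviruses, the mdg1 and mdg3 clade, other gypsy-superfamily elements, Pao/Bel, copia, LINEs, DNA transposons with Helitrons, and telomeric elements. Of the 123 members named, 102 matched entries of the tables; 15 entries were matched by a synonym once the names in the tables were known but before any test.

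The rule for naming entries was written before the data were examined, as were the comparisons and most alternatives. It takes, per knockdown, up to 4 called members of each list by size of change. It adds the 10 largest rises and 5 largest falls among called entries that moved the same way in both libraries against both controls, at a mean of at least 1 CPM. Gypsy, mdg1, 297 (DM297), 412 (DM412 and DM412B), blood, Stalker2 and ZAM are named everywhere. Entries named outside it were chosen after their values were seen. The alternatives were DESeq2 1.42.0 size factors and its Wald test, library sizes alone, no low-count filter, each set fitted alone, a replicate block, all 6 LacZ libraries as control, LacZ of set 1 for set 3, and each library left out. Added after the data were seen were TMM over TE entries alone, scaling without structural RNAs, a fit of all repeats, and LTR and internal parts summed. Groups of 2 allow no test over other splits of the libraries.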

Results

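The comparisons ask which transposable elements (TEs) gain RNA in OSC cells when Piwi, its partner Panx, the SUMO protein Smt3, the SUMO ligase Su(var)2-10, Sov, PNUTS or Setx is knocked down. In the LacZ controls, TE entries took 31.5% ± 1.64 (SD, n = 2), 33.4% ± 0.696 and 29.2% ± 1.01 of the counted repeat reads in sets 1, 2 and 3. The share was 55.9% ± 2.50 and 57.5% ± 2.77 after the pair of Smt3 knockdowns, 44.3% ± 0.520 after Su(var)2-10, 39.9% ± 2.08 after Panx, and 46.4% ± 0.575 after Piwi in set 1. In set 2 it was 50.0% ± 0.533 after Piwi and 63.3% ± 0.174 after Sov. The set 3 knockdowns differed less from their control: 32.3% ± 0.239 after PNUTS, 32.3% ± 0.370 after Setx and 33.5% ± 0.0238 after both.

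**Figure D1:**
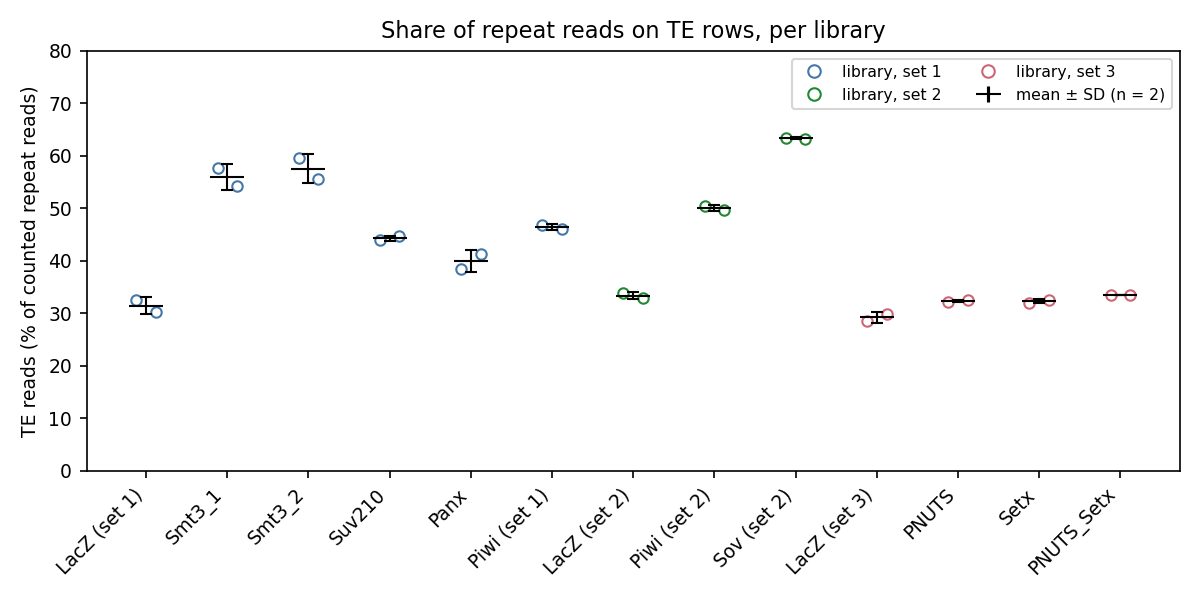
Share of counted repeat reads that fall on TE entries (y axis, percent) in each of the 26 libraries (circles, coloured by set) by knockdown (x axis), with the mean and SD of each group. Sov has the highest mean at 63.3%, and the set 3 groups lie between 29.2% and 33.5%.

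Piwi knockdown raised a limited group of TEs by large factors, and did so in both sets. Of 193 tested TE entries, 75 were called higher and 13 lower in set 1, and 92 higher and 6 lower in set 2. With library sizes alone the counts were 64 and 37, and 62 and 48; with TMM over TE entries alone they were 54 and 68, and 55 and 73. At least 2-fold rises numbered 48 and 54. In set 1, the internal part of gypsy rose 34.8-fold (log2 5.12, SE 0.0702, adjusted p 1.24e-33), from 1122 ± 22.5 to 38996 ± 938 CPM. DM297_I-int rose 44.3-fold (log2 5.47, SE 0.154, adjusted p 4.82e-25). In set 2, gypsy rose 46.8-fold (log2 5.55) and DM412 43.4-fold (log2 5.44, SE 0.0928, adjusted p 4.81e-31). Of the entries called higher, 69 were shared by both sets against 35.8 for independent lists (adjusted p 1.11e-23, one-sided Fisher's exact test), and across entries, which are not independent replicates, the log2 changes correlated with r 0.88 and rho 0.75. Among the falls, the internal part of micropia dropped by 1.82 on the log2 scale in set 1 (adjusted p 1.65e-14) and by 0.34 in set 2 (adjusted p 0.0131).

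Panx knockdown changed many of the same entries. It raised 76 entries, 43 of them at least 2-fold, and lowered 13. With library sizes alone the counts were 72 and 17, and with TMM over TE entries alone 46 and 56. The internal part of gypsy rose 12.7-fold (log2 3.67, SE 0.0666, adjusted p 6.43e-30), and that of Osvaldo 18.4-fold (log2 4.20, SE 0.117, adjusted p 6.62e-25). With Piwi of set 2 it shared 64 raised entries against 36.2 for independent lists (adjusted p 2e-16). Compared directly with Piwi of set 1, Panx left 38 entries lower and 19 higher, but 31 lower and 43 higher with library sizes alone. The internal parts of gtwin and tirant were lower by 2.78 and 2.32 on the log2 scale (log2 -2.78, adjusted p 3.8e-15, and log2 -2.32, adjusted p 3.65e-12), while Osvaldo was higher by 1.00 (adjusted p 1.11e-12). These 3 were chosen after their values were seen.

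Loss of the SUMO protein raised more TE entries than loss of Piwi. The Smt3 knockdowns raised 163 and 166 of 193 entries, 161 of them in common, with 139 and 151 raised at least 2-fold; 14 and 10 fell. The median entry rose by 2.24 and 2.64 on the log2 scale, or by 2.15 and 2.61 with entries at 0 in the control set to their lower bound. Gypsy5_I-int rose 70.5-fold (log2 6.14, SE 0.158, adjusted p 2.01e-26) and 89.4-fold in groups 1 and 2. The rDNA retrotransposon R1 rose 41.3-fold (log2 5.37, SE 0.093, adjusted p 7.66e-31) and 28.0-fold, the latter from 87.6 ± 7.23 to 2463 ± 71.4 CPM. Accord, with 2 counts in the control libraries, reached 1892 counts in group 1, a ratio of 1295 with a 95% counting interval of 358 to 10704. Against this rise, the internal part of blood fell in both groups (log2 -0.88, SE 0.0613, adjusted p 1.03e-14, and log2 -0.60), although it rose 2.32-fold with Piwi in set 1. The DNA transposon pogo fell as well (log2 -0.87, adjusted p 1.67e-12, and log2 -0.97). Group 2 exceeded group 1 in 101 entries and was lower in 10 (35 and 43 with TMM over TE entries alone).

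In the direct contrast with Piwi of set 1, the mean of the Smt3 groups was higher in 151 entries, 121 of them at least 2-fold, and lower in 27; with TMM over TE entries alone it was higher in 75 and lower in 83. The internal part of nomad was higher by 4.91 (SE 0.0805, adjusted p 1.42e-31) and that of batumi by 3.86 (SE 0.0838, adjusted p 1.86e-28). Gypsy itself was lower with Smt3 than with Piwi (log2 -0.61, SE 0.0486, adjusted p 2.87e-13), and so was blood (log2 -1.95, adjusted p 1.79e-26).

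Su(var)2-10 knockdown lay between Piwi and Smt3 in number. It raised 141 entries, 100 of them at least 2-fold, with a median of 1.12 on the log2 scale. Gypsy5_I-int rose 36.2-fold (log2 5.18, SE 0.172, adjusted p 4.49e-23), from 18.2 ± 8.88 to 674.9 ± 31.9 CPM, and the DNA transposon Transib1 42.4-fold (log2 5.40, SE 0.280, adjusted p 5.83e-18). The single fall was of Gypsy12_LTR (log2 -0.18, adjusted p 0.00493); it was not called without LacZ replicate 2 of set 1 (log2 -0.14, adjusted p 0.0671) or without Su(var)2-10 replicate 1 (log2 -0.12, adjusted p 0.107). With all 6 LacZ libraries as control, Gypsy12_LTR changed sign and was not called (log2 0.11). In direct contrasts, 120 entries were higher and 23 lower than with Piwi of set 1. Against Smt3, 22 were higher and 135 lower. With TMM over TE entries alone these were 65 and 67 against Piwi and 84 and 48 against Smt3, and with library sizes alone 146 and 13 against Piwi and 56 and 96 against Smt3.

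Sov knockdown raised 178 entries, 151 of them at least 2-fold, with a median of 2.72. With library sizes alone it raised 150 and lowered 17 (median 1.99), next to 143 and 20 for Smt3 group 1 and 153 and 20 for group 2 (medians 1.66 and 2.11). The LINE Jockey2 rose 247-fold (log2 7.95, SE 0.0946, adjusted p 1.64e-35), from 47.5 ± 1.38 to 11759 ± 288 CPM, and DM412 rose 177-fold (log2 7.47, SE 0.100, adjusted p 2.24e-34), from 497.7 ± 42.4 to 88029 ± 1874 CPM. The 3 falls were of the internal part of diver (log2 -0.49, adjusted p 3.97e-09), TART_B1 (log2 -0.38, adjusted p 8.85e-07) and TART (log2 -0.23, adjusted p 0.000558). Compared with Piwi of the same set, Sov was higher in 169 entries and lower in 8 (83 and 87 with TMM over TE entries alone). Across Piwi in both sets, Panx, both Smt3 groups, Su(var)2-10 and Sov, 53 entries rose in every comparison. In both Smt3 groups, Su(var)2-10 and Sov, 132 rose. Comparisons of the same set share their LacZ libraries, and lists that hold most entries overlap in any case, so part of this is built in.

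**Figure D2:**
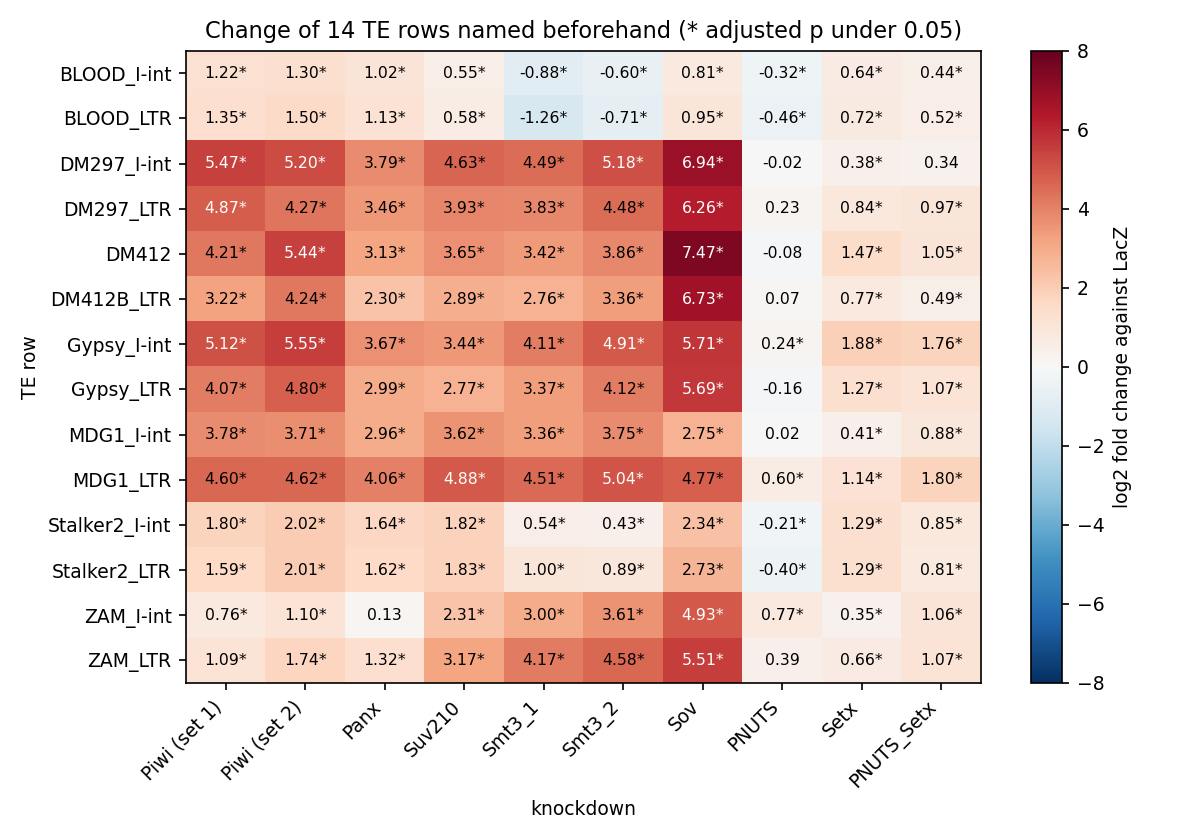
Log2 fold change against LacZ (colour and number) of the 14 entries of gypsy, mdg1, DM297, DM412, blood, Stalker2 and ZAM (y axis) in each knockdown (x axis); an asterisk marks an adjusted p under 0.05. Blood fell in both Smt3 groups (log2 -0.88 and -0.60 for its internal part) and rose with Piwi (log2 1.22 and 1.30). With scaling over TE entries alone, Stalker2 with Smt3 and its internal part with Sov turned negative. So did blood with Su(var)2-10 and Sov, and the internal part of ZAM with Panx. With library sizes alone, the internal part of Stalker2 with Smt3 group 2 turned negative. With LacZ of set 1 as control, the internal parts of gypsy (log2 -0.25) and DM297 (log2 0.61) changed sign with PNUTS. That of ZAM did so with Setx (log2 -0.40). With all 6 LacZ libraries, those of gypsy with PNUTS (log2 -0.057) and of ZAM with Setx (log2 -0.049) changed sign.

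Setx knockdown raised TEs, by smaller factors than Piwi, and PNUTS knockdown raised few against LacZ of set 3. Setx raised 58 entries, 19 at least 2-fold, and lowered 4; these were 41 and 2 with all 6 LacZ libraries as control and 95 and 16 with LacZ of set 1. Osvaldo rose 7.56-fold (log2 2.92, SE 0.110, adjusted p 6.87e-21), from 41.5 ± 0.935 to 314.9 ± 2.53 CPM. The internal parts of tabor and gypsy rose 4.95-fold (log2 2.31, SE 0.0825, adjusted p 2.17e-21) and 3.67-fold (log2 1.88, SE 0.0628, adjusted p 6.18e-22). The 4 falls were of LINEJ1_DM (log2 -0.50), DOC2_DM (log2 -0.35), Circe (log2 -0.34) and Minos (log2 -0.71). With LacZ of set 1 as the control, DOC2_DM (log2 0.56) and Circe (log2 0.34) were called higher; DOC2_DM was not called with all 6 LacZ libraries (log2 0.028), nor was Circe (log2 -0.45). Minos was called with neither of these controls, and was not called without Setx replicate 2 (log2 -0.58, adjusted p 0.0883). PNUTS raised 13 and lowered 15, none of them 2-fold. These were 26 and 11 with TMM over TE entries alone, 3 and 7 with all 6 LacZ libraries as control, and 66 and 28 with LacZ of set 1. Its largest rise was 1.71-fold, of the internal part of ZAM (log2 0.77, SE 0.126, adjusted p 3.15e-05), and its largest fall was of the internal part of frogger (log2 -0.61, SE 0.0618, adjusted p 1.09e-08). The PNUTS count of 28 was 17 without LacZ replicate 1 and 18 without LacZ replicate 2 of set 3. Compared directly, Setx was higher than PNUTS in 60 entries and lower in 11 (43 and 36 with TMM over TE entries alone).

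Knocking down PNUTS with Setx raised about as many entries as Setx alone. It raised 56 entries, 18 at least 2-fold, and lowered 11; these were 40 and 4 with all 6 LacZ libraries as control and 90 and 16 with LacZ of set 1. Osvaldo rose 7.39-fold (log2 2.89, SE 0.111, adjusted p 1.68e-20) and gypsy 3.38-fold (log2 1.76, SE 0.0627, adjusted p 4.15e-21). Against PNUTS alone it was higher in 54 entries and lower in 9 (33 and 27 with TMM over TE entries alone). Against Setx alone it was higher in 10 and lower in 17, a total of 27 that was 16 without Setx replicate 1. The double effect differed from the sum of the single effects in 4 entries; it did so in 13 with set 3 fitted alone, and in 2 families with LTR and internal parts summed. It was smaller for the internal parts of tabor (log2 -0.74, adjusted p 0.000112) and gypsy (log2 -0.36, adjusted p 0.0165) and for Invader1_LTR (log2 -0.94, adjusted p 0.0165). It was larger for the internal part of mdg1 (log2 0.45, adjusted p 0.0165). These differences were not computed with other controls, which would shift them. The PNUTS change of the internal part of gypsy turned negative with LacZ of set 1 (log2 -0.25). It did so with all 6 LacZ libraries too (log2 -0.057). A single call remained without any one of LacZ replicate 1 of set 3, PNUTS replicate 2, Setx replicate 1 or double-knockdown replicate 2.

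The entries raised by Setx were mostly ones that Piwi knockdown raised in another set. With Piwi of set 2, Setx shared 54 of its 58 raised entries, against 27.6 for independent lists (adjusted p 3.59e-17, one-sided Fisher's exact test). The test treats entries as independent, but the LTR and internal part of an element are linked, so its p-values overstate the evidence. The double knockdown shared 52 of 56 (adjusted p 2e-16), and PNUTS 8 of 13 against 6.2 (adjusted p 0.305). Over the 92 entries that Piwi raised in set 2, the median log2 change was 1.37 in the Piwi comparison that picked them. It was 1.09 with Piwi in set 1, 0.35 with Setx, 0.34 with the double knockdown and 0.014 with PNUTS. Over the other 101 entries it was -0.022 with Setx. Su(var)2-10 shared 80 entries with Piwi against 67.2 (adjusted p 8.44e-05). For both Smt3 groups (80 against 77.7, adjusted p 0.305, and 82 against 79.1, adjusted p 0.266) and for Sov (72 against 69.2, adjusted p 0.193), overlap with Piwi was near that of independent lists. Their lists hold most entries, which leaves little room for an excess.

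**Figure D3:**
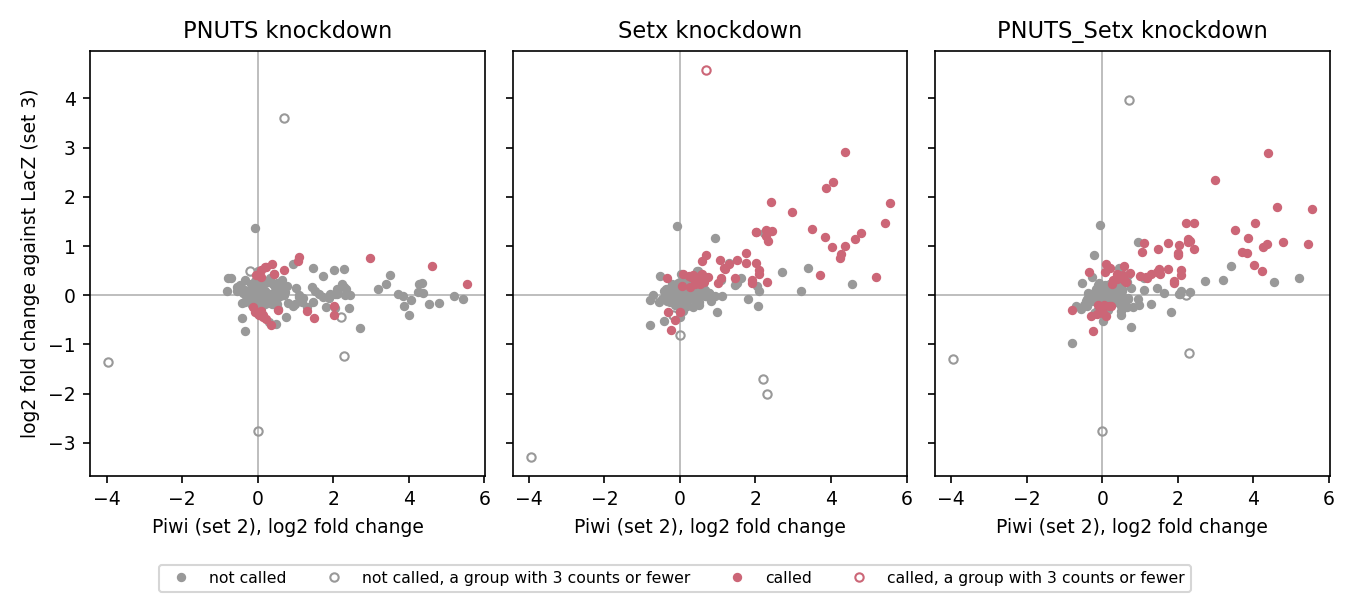
Log2 fold change against LacZ of set 3 (y axis) of each of 193 TE entries with knockdown of PNUTS, Setx or both (panels), against the log2 fold change with Piwi in set 2 (x axis); coloured points were called, and open points have a group with 3 counts or fewer, so that their positions are not measured folds. Entries far right rise with Setx (median 0.35 over the 92 raised by Piwi) and not with PNUTS (median 0.014); with scaling over TE entries alone, Setx called 42 entries higher and 24 lower, and the double knockdown 51 and 27.

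Of the 8 fixed lists, the errantivirus and mdg1/mdg3 lists had the highest medians with every knockdown but PNUTS. Together they held 36 of the 75 entries raised with Piwi in set 1, 37 of 92 in set 2 and 27 of 58 with Setx. Most of the raised entries thus lay outside them, but the lists have only 26 and 18 of the 193 tested entries. Camera with its preset correlation set the mdg1/mdg3 list above the other TE entries for Setx (adjusted p 2.72e-08) and Piwi in set 2 (adjusted p 2.66e-10), but with an estimated correlation none of its 20 calls over all lists and knockdowns held (adjusted p 0.171 and 0.0598 for this pair). The following counts are entries called higher over all TE entries tested. Of 26 errantivirus entries, 21 and 22 rose with Piwi in sets 1 and 2, 18 with Panx, 25 with each Smt3 group, 24 with Su(var)2-10, 26 with Sov, 13 with Setx, 12 with the double knockdown and 2 with PNUTS. Adjusted over the list alone, the Panx count was 19 and the others were the same. Of 18 mdg1/mdg3 entries, 15 rose with Piwi in each set, 13 with Panx, 16 with each Smt3 group, 15 with Su(var)2-10, 18 with Sov, and 14 with Setx and with the double knockdown; PNUTS raised 1 and lowered 4. The median changes of both lists stayed above 0 in these comparisons, PNUTS aside, under every scaling tried. LINEs rose in 8 and 12 of 28 entries with Piwi, 10 with Panx, 27 with each Smt3 group, 24 with Su(var)2-10, 28 with Sov, 6 with Setx and with the double, and 1 with PNUTS. Their medians with Piwi of 0.27 and 0.17 and with Panx of 0.36 became -0.30, -0.26 and -0.23 with scaling over TE entries alone.

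Other gypsy-superfamily entries rose in 4 and 6 of 36 with Piwi, 5 with Panx, 30 and 31 with Smt3, 24 with Su(var)2-10, 34 with Sov, 3 with Setx, and 4 with PNUTS and with the double. Copia entries rose in 0 and 3 of 8 with Piwi, 0 with Panx, 7 and 8 with Smt3, 5 with Su(var)2-10, 8 with Sov, 2 with Setx, 1 with the double and 2 with PNUTS, which lowered 4. Pao/Bel entries rose in 4 and 5 of 16 with Piwi, 5 with Panx, 11 with each Smt3 group and with Sov, 9 with Su(var)2-10, 3 with Setx, 2 with the double and 1 with PNUTS. DNA transposons and Helitrons rose in 7 and 8 of 16 with Piwi, 7 with Panx, 12 and 13 with Smt3, 12 with Su(var)2-10, 13 with Sov, 3 with Setx and with the double, and 0 with PNUTS. Of 4 telomeric entries, 2 and 0 rose with Piwi, 3 with Panx and with each Smt3 group, 1 with Su(var)2-10, 2 with Sov, 0 with Setx, and 1 with PNUTS and with the double. With all 6 LacZ libraries as control, TART and TART_B1 had negative changes with Piwi in set 1 (log2 -0.54 and -0.88, the latter called lower), as did TART_B1, TART and HETA with Panx (log2 -0.52, -0.28 and -0.30), HETA and TART with Smt3 (log2 -0.18 and -0.21 in group 1, -0.11 and -0.41 in group 2), and HETA with Su(var)2-10 (log2 -0.31). With scaling over TE entries alone, the medians of the telomeric list were below 0 for every knockdown but PNUTS, and those of the Pao/Bel and DNA lists were below 0 for Piwi, Panx, Smt3, Su(var)2-10 and Sov. The other gypsy-superfamily list had medians of 0.54 and 0.61 with Smt3, 0.64 with Sov and -0.22 with Su(var)2-10 on that scale.

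Some entries of the lists fell, by the same test. Of the other gypsy-superfamily entries, 6 and 2 fell with Piwi, 5 with Panx, 3 with each Smt3 group and with the double, 2 with PNUTS, and 1 with Su(var)2-10 and with Setx. Pao/Bel entries fell in 2 and 3 cases with Piwi, 3 with Panx, 2 and 1 with Smt3 and 1 with Sov, and 2 copia entries fell with Panx. Of the telomeric entries, 2 fell with Sov, with PNUTS and with the double, and 1 with each Smt3 group. With LacZ of set 1 as control, TART and TART_B1 were called higher with PNUTS (log2 0.70 and 1.16). They were called higher with the double too (log2 0.74 and 1.198). Of the mdg1/mdg3 entries, 1 fell with Piwi in each set and with Panx, and 2 with each Smt3 group. Of the errantivirus entries, 1 fell with each Smt3 group. LINEs fell in 2 cases with Setx and with the double, and in 1 with Piwi in set 1, Smt3 group 1 and PNUTS. A DNA entry fell with Piwi in set 1, each Smt3 group, PNUTS and the double. The remaining pairs of list and knockdown had no fall beyond those of PNUTS given above.

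Adjusted over each list alone, most counts of raised entries were the same. Other gypsy-superfamily counts became 3 and 5 with Piwi and 4 with Panx. DNA counts became 13 with Su(var)2-10, 1 with Setx and 2 with the double knockdown, and the LINE count with the double became 5. With PNUTS, the mdg1/mdg3 count became 2 and the Pao/Bel count 0. Median and mean of a list differed in sign in 8 of 80 cases, with medians within 0.063 and means within 0.11 of 0.

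The controls of different sets were not interchangeable. LacZ of set 2 differed from LacZ of set 1 in 98 entries (76 higher), and LacZ of set 3 in 88 (65 higher); TART_B1, chosen after its value was seen, was higher by 1.34 and 1.41 on the log2 scale. Folds are relative to the other repeat RNA: with TMM over TE entries alone, the median entry shifted by -2.11 and -2.40 with Smt3, -1.22 with Su(var)2-10, -2.47 with Sov, -0.58 and -0.49 with Piwi, -0.58 with Panx and -0.13 with Setx. With library sizes alone, it shifted by -0.57 and -0.52 with Smt3, -0.73 with Sov, and -0.24 and -0.35 with Piwi.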

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

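Most of the tests weighed here were chosen only after the result was seen. They are those of TMM scaling, of genomic DNA background, of Smt3 acting beyond Piwi and of precision. Those of the choice of LacZ libraries, of PNUTS knockdown strength and of Setx acting on Piwi-sensitive entries were chosen so too.

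The effect of Piwi knockdown differed between the sets in 25 TE entries by a direct test of the difference. It was higher in set 2 for 22 of them, most of all for R1_DM (log2 1.90, adjusted p 1.91e-09), MICROPIA_I-int (log2 1.47, adjusted p 9.45e-08) and DM412 (log2 1.23, adjusted p 1.91e-09). With library sizes alone, 15 were higher and 10 lower. In the fit reported, it was lower for Gypsy1-I_DM (log2 -0.50), Gypsy1-LTR_DM (log2 -0.39) and TART_B1 (log2 -0.29). All 6 were chosen after their values were seen. Without 1 library, 17 to 26 entries were called, 17 without LacZ replicate 2 of set 2.

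The double knockdown of PNUTS and Setx differed from the sum of the single effects in 4 entries, by the interaction term. It did so in 13 entries with set 3 fitted alone, and in 2 families with LTR and internal parts summed. The interaction was not computed with other controls, which would shift it. With PNUTS, the change of Gypsy_I-int turned negative with LacZ of set 1 (-0.25) and with all 6 LacZ libraries (-0.057). The changes with PNUTS, Setx and both were -0.090, 2.31 and 1.47 for TABOR_I-int, 0.020, 0.41 and 0.88 for MDG1_I-int, 0.24, 1.88 and 1.76 for Gypsy_I-int, and 0.52, 0.82 and 0.40 for Invader1_LTR. A single call was left without LacZ replicate 1 of set 3, PNUTS replicate 2, Setx replicate 1 or double-knockdown replicate 2, and the cause was not tested.

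Repeats outside the TE entries also changed at least 2-fold against their LacZ controls, although no comparison was planned for them. XDMR rose with Piwi (log2 1.88 in set 1 and 2.44 in set 2), Panx (1.96), Smt3 group 2 (1.86) and Sov (2.24). The satellite SAR_DM rose with Smt3 (3.05 and 2.89), Su(var)2-10 (2.87) and Sov (1.70). M4DM rose with Smt3 (1.31 and 1.29) and Sov (1.35), DMRP1 with Smt3 group 1 (1.60), and the satellite DMSAT6 with Sov (1.70). Of the entries grouped here as structural RNAs, NTS_DM rose with Smt3 group 2 (1.195) and Sov (1.72), and LSU-rRNA_Dme with Sov (1.21), from 5125 to 11869 CPM. TLD2 rose with Piwi in set 2 (2.59) and Sov (9.16, from 3.36 to 1942 CPM). The fitted values of TLD2 with Smt3 (5.46 and 6.87) and Su(var)2-10 (3.63) rest on 3 control counts; the ratios there were 46.6 (95% counting interval 15.5 to 229), 123 (41.7 to 602) and 13.0 (4.13 to 66.0). Other such repeats fell. SSU-rRNA_Dme fell with Smt3 (-1.39 and -1.33) and Su(var)2-10 (-1.40), HETRP_DM with Piwi in set 1 (-1.13) and Panx (-1.08), and ARS406_DM with Piwi in set 1 (-1.09), Panx (-1.19), Smt3 group 2 (-1.47) and Su(var)2-10 (-1.23). All 9 falls are against LacZ of set 1. In that control ARS406_DM stood at 62.5 CPM, against 19.5 and 26.8 in LacZ of sets 2 and 3. The knockdowns named for it had 22.2 to 29.9 CPM, and Piwi in set 2 changed it by 0.13 (not called). SSU-rRNA_Dme was lower in every set 1 knockdown, Piwi (-0.78) and Panx (-0.74) included. A high level in LacZ of set 1 cannot be told apart from an effect of these knockdowns.

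Most TE entries rose in both Smt3 groups and in Sov. The tables argue against TMM scaling as the source: with library sizes alone, the lowest median change of the 3 comparisons was 1.66 on the log2 scale. They argue against a uniform lift of all TE entries from a fall of other RNA as the only source. At most 21.2% of entries lay within 0.5 log2 of the median. A uniform lift on top of other changes would leave this spread as it is, so it stays open as a part of the rise. Reads from genomic DNA would add about the same CPM per kb to every entry. Unspliced background need not do so, and the following test cannot weigh it. At most 37.3% of entries gained within 2-fold of the median, a share between the bounds of 25 and 50 set for this test. An earlier test, Spearman's rho of the gain with length, gave 0.55, 0.56 and 0.54, between its bounds as well. Background therefore stays open as a part of the rise, although 10.4%, 8.29% and 4.15% of entries lost CPM. Of the 101 entries not raised with Piwi in set 2, 87.1% were higher with Smt3 than with Piwi of set 1, against 78.2% of all entries. Here the entries were picked with other libraries than those contrasted. A first test, which picked 95 entries with Piwi of set 1 too, gave 87.4%. The Piwi changes of both sets correlated (r 0.88), so picking entries that Piwi left favours a higher Smt3 value in either test. The excess over 78.2% is thus no separate support. These shares rest on scaling over all repeats. With scaling over TE entries alone, which centres them, the contrast of Smt3 with Piwi called 75 of all entries higher and 83 lower. Smt3 loss may act on TEs beyond those that depend on Piwi, a hypothesis found and tested on the same data. An incomplete knockdown of Piwi could give the same contrast, and how well each knockdown worked is unknown.

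The LacZ libraries of sets 1 and 2 differed in 98 entries. Counting noise of low entries is argued against, since 14.3% of the called entries had a mean under 50 counts per library. The Piwi libraries of the same sets differed along with their controls (Pearson r 0.545, Spearman's rho 0.58 over 193 entries, which are not independent replicates). A difference shared by the libraries of a set may thus explain part of it. Whether it lies in the cells, the libraries or the sequencing is not in the labels, and no biological explanation was tested.

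Setx knockdown raised 58 entries and PNUTS knockdown 13. The median standard error with PNUTS was 1.05 times that with Setx. The fit shares the spread of an entry over all libraries, so this ratio cannot show a wider spread with PNUTS. Between the replicates of each group, chi-square over degrees of freedom was 1.54 with PNUTS and 1.33 with Setx. A wider spread alone would not move a typical change towards 0. Over the 92 entries raised with Piwi in set 2, the median log2 change was 0.014 with PNUTS and 0.35 with Setx. For these entries, this argues against lower precision as the only source. The choice of LacZ libraries as the only source is argued against by a contrast without LacZ. In it, 60 entries were higher with Setx than with PNUTS (43 higher and 36 lower with scaling over TE entries alone). That PNUTS was knocked down less than Setx stays open, because the tables have 0 entries for either gene. Setx shared 1.95 times as many raised entries with Piwi as independent lists would. Setx loss may act on TEs that also respond to Piwi loss, again as a hypothesis from the same data. A weaker knockdown of PNUTS could give the same contrast.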

How the results depend on the processing

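The contrasts of Panx, Smt3, Su(var)2-10 and Sov with Piwi, of Su(var)2-10 with Smt3 and of Setx with PNUTS were chosen after the first results were seen. So were TMM over TE entries alone, scaling without structural RNAs, the fit of all repeats and the sums per family. A count of called entries is treated as kept when it lies within 1.5 times the count reported.

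All 23 counts were kept with DESeq2 size factors, the DESeq2 Wald test, library sizes alone, no low-count filter, a fit of all repeats, and scaling without structural RNAs. Of the log2 changes of single named entries, 413 of 415 kept direction and side of the threshold with DESeq2 size factors, 396 with the Wald test, 410 without a filter, 388 with all repeats and 415 without structural RNAs. The others kept their direction, and 2, 19, 4 and 27 of them were no longer called with the first 4 of these settings. With each set fitted alone, 401 of 408 were kept.

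A replicate block within sets kept all 23 counts (Piwi 88 and 97, Panx 88, Su(var)2-10 142, Sov 181, PNUTS 24, Setx 59, double 64), and 401 of 415 named changes. Whether equal numbers mark paired libraries was checked with the correlation of differences between the replicates of 2 groups. It ran from -0.044 to 0.30 in set 1, from -0.068 to 0.16 in set 2 and from -0.34 to 0.19 in set 3. It exceeded 0.1 in 6 of 15 pairs in set 1, 1 of 3 in set 2 and 1 of 6 in set 3. The numbers show no clear pairing, but a weak shared effect in set 1 stays possible.

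Leaving out 1 library kept 97 of 104 counts and 1545 of 1660 named changes, with no reversal. The lone library left in a group is then assumed to vary like the other groups. PNUTS went from 28 calls to 17 to 19: 17 without LacZ replicate 1 and 18 without LacZ replicate 2 of set 3. The double against Setx went from 27 to 16 to 21, the lowest without Setx replicate 1. The interaction went from 4 to 1 to 4. It was 1 without LacZ replicate 1 of set 3, PNUTS replicate 2, Setx replicate 1 or double-knockdown replicate 2. The cause was not tested. The interaction calls numbered 13 (4 higher, 9 lower) with the libraries of set 3 fitted alone, 4 of them shared with those reported. With LTR and internal parts summed into 136 families they numbered 2, and the cause was not tested.

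The choice of control changed counts and directions. With all 6 LacZ libraries, PNUTS had 10 calls (3 higher, 7 lower; 9 shared with those reported) and the double 44 (43 shared). With LacZ of set 1 in place of set 3, PNUTS had 94 (66 higher; 8 shared), Setx 111 (95 higher; 49 shared) and the double 106 (90 higher; 50 shared). By construction, this adds the difference between the controls to each change, and 21 of 111 named changes reversed. With PNUTS they were Gypsy_I-int (-0.25), R1_DM (-0.84), G5_DM (0.22), Copia_I-int (-0.30), Copia_LTR (-0.034), Invader4_LTR (-0.45), Invader6_I-int (-0.49), TRANSPAC_LTR (0.053), TART (0.70), TART_B1 (1.16) and DM297_I-int (0.61). With Setx they were TRANSPAC_I-int (-0.029), CIRCE (0.34), DOC2_DM (0.56) and ZAM_I-int (-0.40). With the double they were Copia_I-int (-0.60), Invader4_LTR (-0.34), Invader4_I-int (-0.84), TART (0.74), TART_B1 (1.198) and CIRCE (0.27).

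With all 6 LacZ libraries, 26 of 415 named changes reversed, again through the difference between controls. They were TV1I (-0.22), TART (-0.54) and TART_B1 (-0.88) with Piwi in set 1, and DIVER2_LTR (-0.22), Copia_LTR (0.019), Copia_I-int (0.18), TART_B1 (-0.52), TART (-0.28) and HETA (-0.30) with Panx. HETA and TART reversed with Smt3 group 1 (-0.18 and -0.21) and group 2 (-0.11 and -0.41), and HETA (-0.31) and Gypsy12_LTR (0.11) with Su(var)2-10. In set 3 they were Gypsy_I-int (-0.057), R1_DM (-0.18), Invader4_LTR (-0.068), Invader6_I-int (-0.050) and TART_B1 (0.12) with PNUTS. With Setx they were TRANSPAC_I-int (-0.0047), DOC2_DM (0.028) and ZAM_I-int (-0.049), and with the double Copia_I-int (-0.086), Invader4_I-int (-0.24) and TART_B1 (0.15).

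Scaling decides how many TE entries are called higher and how many lower. TMM over TE entries alone sets their typical change near 0 by construction, so it cannot show a rise of most TEs. It gave 54 higher and 68 lower with Piwi in set 1, 55 and 73 in set 2, 46 and 56 with Panx, 81 and 69 and 83 and 75 with Smt3, 68 and 68 with Su(var)2-10, 93 and 80 with Sov, 26 and 11 with PNUTS, and 42 and 24 with Setx. The difference between the Piwi effects went from 25 to 38 calls; the cause was not tested. By the shift of all entries, 30 of 406 named changes reversed. They were MAX_I-int (-0.069), ROOA_I-int (-0.11), TART (-0.37) and TART_B1 (-0.43) with Piwi in set 1, and Copia_LTR (-0.055), Copia_I-int (-0.095) and FROGGER_I-int (-0.14) in set 2. With Panx they were TART_B1 (-0.062), TART (-0.10), HETA (-0.14) and ZAM_I-int (-0.46). With Smt3 group 1 they were HETA (-1.45), TART (-1.46), Stalker2_I-int (-1.49) and Stalker2_LTR (-1.03), and with group 2 TAHRE (-0.41), HETA (-1.75), TART (-2.04), Stalker2_LTR (-1.51) and Stalker2_I-int (-1.96). With Su(var)2-10 they were HETA (-0.77), BLOOD_I-int (-0.66) and BLOOD_LTR (-0.64). With Sov they were TRANSIB3 (-0.31), DM1731_LTR (-0.051), TAHRE (-1.78), HETA (-2.05), Stalker2_I-int (-0.10), BLOOD_LTR (-1.49) and BLOOD_I-int (-1.63).

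In direct contrasts this scaling gave 75 higher and 83 lower for Smt3 against Piwi, 65 and 67 for Su(var)2-10 against Piwi, 84 and 48 for Su(var)2-10 against Smt3, 83 and 87 for Sov against Piwi, and 43 and 36 for Setx against PNUTS.

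Library sizes alone kept the totals but not each balance of higher and lower. They gave 64 higher and 37 lower with Piwi in set 1, 62 and 48 in set 2, 15 and 10 for the difference between the Piwi effects, 43 and 31 for Panx against Piwi, 56 and 96 for Su(var)2-10 against Smt3, 143 and 20 and 153 and 20 for the Smt3 groups, and 150 and 17 for Sov. By the change of scale, 7 of 410 named changes reversed: TART (-0.020) and TART_B1 (-0.078) with Piwi in set 1, FROGGER_I-int (-0.0011) in set 2, TART (-0.16) and Stalker2_I-int (-0.089) with Smt3 group 2, and TAHRE (-0.073) and HETA (-0.34) with Sov. Camera with an estimated correlation kept 60 of 80 list results, and the 20 that had been called were not called.

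Scaling over genes alone, and every result on genes or single TE copies, could not be computed, since the tables have neither. With 679372 to 1971951 repeat reads per library, entries with a few counts in the control have wide intervals: 358 to 10704 around the ratio of 1295 for ACCORD_I-int with Smt3 group 1.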

Other observations

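The counts in this part were all made after the first results were seen.

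The LTR and the internal part of 57 elements were counted separately. Their log2 changes correlated with r 0.86 and 0.89 with Piwi, 0.72 with Panx, 0.62 and 0.61 with Smt3, 0.65 with Su(var)2-10, 0.68 with Sov, 0.53 with Setx, 0.44 with the double knockdown and 0.42 with PNUTS. Both parts were called the same way in 19 and 24 elements with Piwi, 19 with Panx, 46 and 47 with Smt3, 33 with Su(var)2-10, 52 with Sov, 12 with Setx and with the double, and 5 with PNUTS. One part alone was called in 19 and 14 with Piwi, 17 with Panx, 7 and 4 with Smt3, 14 with Su(var)2-10, 4 with Sov, 17 with Setx and with the double, and 11 with PNUTS. They were called opposite ways in 3 elements with each Smt3 group, in 1 each with Piwi in set 2, Panx and Su(var)2-10, and in 0 with Piwi in set 1, Sov, PNUTS, Setx and the double knockdown.

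Simple repeats, which make up most of the reads outside TEs, changed as well. Of 2245 tested in a fit of simple repeats alone, 24.7% and 25.7% were called with Smt3, 32.1% with Sov and 16.4% with Su(var)2-10. The share was 7.31% and 7.53% with Piwi, 7.57% with Panx, 2.14% with Setx, 3.03% with the double knockdown and 0.846% with PNUTS. Between LacZ groups it was 17.1% for set 2 against set 1 and 30.2% for set 3 against set 1. Their median change lay between -0.092 with Smt3 group 2 and -0.0048 with Piwi in set 1 over the 10 knockdowns.

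Structural RNAs took 4.91% ± 1.35 of the repeat reads in LacZ of set 1 and 2.12% to 3.39% in the knockdowns of that set. In LacZ of sets 2 and 3 they took 1.42% ± 0.0023 and 0.555% ± 0.0855. Of the 193 TE entries, 2 were called in no knockdown, and 10 were called lower in both Smt3 groups.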
